A study of Drosophila melanogaster with 3 samples.

How the data were processed

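Whole embryos of Drosophila melanogaster carrying a GFP-tagged protein, aged 0 to 24 h, were profiled by ChIP-seq with an antibody against GFP in 3 biological replicates, per the labels. Chromatin was fragmented by sonication to 200 to 800 bp, per the labels. The label fields for source and antibody name CG7357 (Odj) and the description names danr; the group was taken from the source label. The labels give the replicate numbers. They call the replicates biological, without saying whether separate collections were used, so the spread between them may be partly technical. The assembly is dm6, per the labels and the file descriptions deposited with the lists. The aligner, the peak caller and their versions are not given in the sources used here.

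The authors deposited 2 kinds of peak list, ranked and thresholded by IDR (the irreproducible discovery rate, a measure of whether peaks keep their rank between 2 lists). For a list of 1 replicate, passing the threshold is not taken here as agreement with another replicate. Ranked and thresholded lists exist per replicate and for the whole series, and the deposited file descriptions derive the latter from alignments of the replicates and a control. The score in the deposited lists is a whole number, and every thresholded entry had a score of 830 or more. The signal in the deposited lists is the value that the authors' caller gave each peak, and its scale and normalization are not given in the sources used here. Lists of the whole series were assigned to replicates by the coordinates of the underlying peaks that each entry carries. The list named conservative was ranked by replicates 2 and 3, the others by replicates 1 and 2, replicates 1 and 3, and a pooled list with the most peaks. The places and signals of all 4 match the pooled data of the 3 replicates, so a list without a replicate leaves it out of the ranking only. The share of entries with coordinates of the assigned replicate was 52.3% to 65.9%, and at most 0.00135% for the replicate left out. All entries of each series list past the threshold were present in its ranked list. No read counts are in the lists used, so depth is unknown and no value has a counting interval from reads; Wilson intervals at 95% cover only the number of peaks or genes.

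Peak coordinates were compared with the Release 6 genome sequence and the Ensembl release 115 annotation of BDGP6.54, which have the coordinates of dm6; coordinates are printed counting from 1. Start sites were those of all annotated transcripts outside transposable elements. Peaks on scaffolds outside 2L, 2R, 3L, 3R, X, 4 and Y (21 of 3348 conservative peaks) were left out of location, gene and sequence results. A promoter peak has its summit within 500 bp of a start site. Exon, intron and intergenic classes were given to the other summits in that order. Pericentric intervals were 2L from 22 Mb, 2R to 5.6 Mb, 3L from 23 Mb, 3R to 4.2 Mb and X from 22.5 Mb, set as approximate bounds. The main tests, gene lists, rule for named genes and most other settings were fixed before the data were examined. Sequence classes, summit positions, shares by signal, gene families and divergent neighbours were chosen after seeing the data.

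Overlap of at least 1 bp counted as shared, and the smaller list of a pair was counted. Overlaps, promoter, tRNA and pericentric shares and density ratios were tested with 1000 random placements over sequence without N, within the same arm for overlaps, promoters and tRNA genes and over the arms compared for the rest. The smallest p is 0.001 one-sided and 0.002 two-sided. Gene lists (14, all members matched to the annotation, a few by older symbols) were compared with all other protein-coding genes by Fisher's exact test, and the 8 sequence elements and all 7-base words present in at least 10 peaks by the exact McNemar test, each with Benjamini-Hochberg adjustment at 0.05. Older symbols shared by 2 genes put caps, Nos and br in the lists for Cadps, nanos and pzg, a name pattern took in RpL24-like, RpL7-like and RpLP0-like, and Lsd-2 was listed by mistake. The main values keep these members. Named were the 25 conservative peaks with the highest signal among those overlapped by thresholded peaks of all 3 replicates, each by its nearest start site; up to 4 genes with the strongest peaks in each gene list; the 5 words with the lowest p that share no 5-base core; and Odj and danr whatever their values.

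Alternatives fixed beforehand were the pooled list, the list without each replicate, the upper 50% of peaks by signal, start-site windows of 250 and 1000 bp, 1 start site per gene, ranked peaks below the threshold as background, pericentric bounds moved by 1 Mb, other overlap rules (summits within 100 bp, 50% of the length), other sequence windows and flanks, words of 6 and 8 bases and locus windows of 20 and 80 kb. Added after seeing the data were merging of overlapping entries, gene lists with the 7 wrong members replaced or left out, an A/T-matched flank (the window starting 250 to 600 bp away, in steps of 25 bp, with the closest A/T content), a flank of exactly the same A/T count for words and elements, and scans of longer words. The scripts were tested on simulated data. Random peaks passed the promoter test in 1 of 40 simulations and peaks planted at start sites in 40 of 40. No word of 8189 was called in random windows, both planted words were recovered, and 13 others, among 8188, were called with them. Among random gene sets 1 of 14 was called, and the 1 planted set was. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.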

Results

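Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The flies carried a GFP-tagged protein, which was precipitated with an antibody against GFP. Chromatin had been sheared by sonication to 200 to 800 bp. There were 3 biological replicates of a single group, so the data hold no contrast between conditions, and the questions are where the protein lay, near which genes, and how well the replicates matched. The labels name the tagged gene in conflicting ways. The source, strain and antibody labels give CG7357, the gene Odj (Oddjob), a ZAD zinc finger protein known from heterochromatin. The free-text description gives danr. The replicates were grouped by the source label and the conflict was left open. Depth is unknown, because the files used here are peak lists without read counts. Each peak's signal and score are the authors' own values and served mostly to rank, filter or describe peaks within 1 list. The exceptions were correlations of signal between replicates, a check of where the series lists come from and 1 alternative with a common median signal.

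Replicate 2 had 3014 peaks past the authors' IDR threshold in its own list, against 1891 in replicate 1 and 1889 in replicate 3. The mean was 2265 ± 649 (SD, n = 3). Most peaks of the smaller list of each pair had a partner in the other list. Of the peaks of replicate 1 on the chromosome arms, 89.7% overlapped a peak of replicate 2 by at least 1 bp, where random placement on the same arm gave a mean of 1.37%. Of the peaks of replicate 3, 88.2% overlapped a peak of replicate 2 and 75.8% overlapped a peak of replicate 1, with 1.33% and 0.863% by random placement. Neither other list overlapped 1075 peaks of replicate 2. Draws from the replicates' ranked peaks in place of random positions gave higher means, 3.71%, 3.98% and 2.54% in the same order. Each overlap had a one-sided permutation p of 0.001, the smallest that 1000 placements can give. Strong sites in 1 replicate were strong in the others. Spearman's rho of the signal over shared peaks was 0.811 for replicates 1 and 2 (1681 peaks), 0.866 for replicates 1 and 3 (1423 peaks) and 0.843 for replicates 2 and 3 (1656 peaks). These correlations are across peaks, which are not independent replicates, and carry no p-value.

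The list that the authors named conservative held 3348 peaks, ranked by the peaks of replicates 2 and 3, whose coordinates its entries carry. Its own places and signals match pooled data: 99.7% of the entries have the same place and signal in the pooled list, and among 827 of the strongest the median signal was 0.999 times the sum over the 3 replicates. Thresholded peaks of all 3 replicates overlapped 1407 of them, 42.0% (95% Wilson interval 40.4 to 43.7). Replicate 1 overlapped 1767 of them, which is no independent check, given that sum. A further 592 peaks were overlapped by no single-replicate thresholded list. Among the 1674 peaks with the highest signal, the share found in all 3 replicates was 77.8%. A higher share there is partly built in, because the signal matches the sum over the replicates.

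Promoters were the main location. Of the 3327 conservative peaks on the chromosome arms, 1671 (50.2%) had their summit within 500 bp of an annotated transcription start site (TSS). Random placement on the same arm gave 13.6%, so the share was 3.7-fold higher (permutation p = 0.002, two-sided, the smallest that 1000 placements can give). Over the lists of single replicates the share was 56.0% ± 4.51 (SD, n = 3). The classes of sequence, the summit positions and the shares by signal that follow were chosen after the data were seen. Exons outside promoters held 2.65% of summits and introns 32.7%, where 100 random placements gave means of 19.9% and 39.5%. Intergenic sequence held 14.4%, against 27.0%. Annotated transposable elements held 1.26%, against 6.05%. Promoter summits lay mostly just upstream of the start site. The median position was -104 bp, the quartiles were -184 and -40 bp, and 80.8% lay upstream. The promoter share was 37.4% in the 832 peaks with the lowest signal and 74.4% in the 832 with the highest (95% Wilson intervals 34.2 to 40.7 and 71.3 to 77.2).

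**Figure D1:**
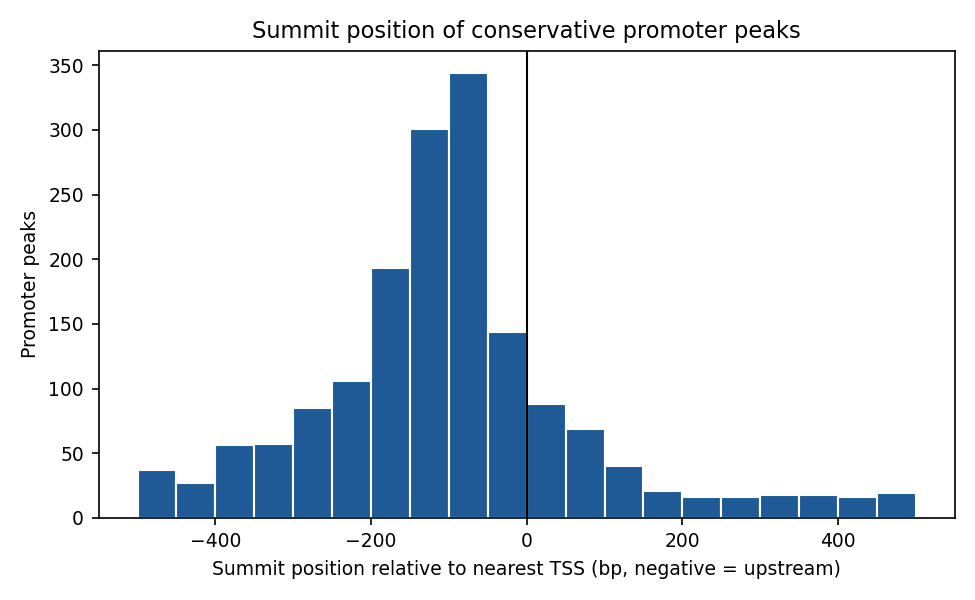
Summit position of the 1671 conservative promoter peaks relative to the nearest TSS in bp, in bins of 50 bp, with negative values upstream and the vertical line at the start site. The tallest bin, 50 to 100 bp upstream, holds 344 peaks.

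The 25 strongest peaks found in all 3 replicates lay almost entirely at promoters. Of these, 24 were promoter peaks, with summits 3 to 157 bp from the start site, and 15 lay within 500 bp of start sites of at least 2 genes. All coordinates are on dm6. The strongest lay upstream of Ptpa (FBgn0016698), an activator of protein phosphatase 2A, on 2L from 3376650 to 3377094. Its signal was 2558 and its summit lay 122 bp upstream of the start site, outside annotated genes, in the sequence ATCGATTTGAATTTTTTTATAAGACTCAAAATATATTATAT. The neighbouring CG9662 also starts within 500 bp. The next was at Ugalt (FBgn0024994), a UDP-galactose transporter, on X from 2703709 to 2704049, with a signal of 2379.5 and its summit 34 bp upstream. The third was at Atg9 (FBgn0034110), an autophagy protein, on 2R from 16294029 to 16294474, with a signal of 2309.8 and its summit 118 bp upstream. In the single-replicate lists these stood at a mean signal percentile of 99.9 ± 0.0917 for Ptpa, 99.9 ± 0.114 for Ugalt and 99.9 ± 0.0461 for Atg9 (SD, n = 3). These peaks were chosen by a signal that matches the sum over the 3 replicates, so high ranks in each are largely built in.

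Among the 25 were mor, a subunit of the Brahma remodelling complex (3R, 15972820 to 15973293, signal 2139), MED21 of the Mediator complex (3L, 25115803 to 25116198, signal 2099) and Hcf, a chromatin cofactor (4, 359679 to 360037, signal 2092). Taf7 of the TFIID complex (3R, 7907330 to 7907711, signal 1789.5) and TH1 of the negative elongation factor (X, 16391353 to 16391750, signal 1821) were also among them. Nuclear genes for mitochondrial proteins were Mrm2 (signal 1931), UQCR-11 (signal 1769) and mRpL41 (signal 1726). Start sites of Ire1 and lncRNA:CR44463 also lay within 500 bp of the summits at Mrm2 and mRpL41, respectively. The proton pump subunit Vha16-1 had a peak of signal 1908 and the RNA helicase gene kz one of 1909. The summit at Faf2 (2L, 18708482 to 18708912, signal 2094) lay 3 bp downstream of the start, in a 5' UTR exon. The 1 peak outside promoters lay in an intron of ush, 1396 bp upstream of the transcription factor gene cbt (2L, 480924 to 481250, signal 2005). The other 10 were at CG14100, FBgn0010877, lncRNA:CR44209, bdg, mthl1, Traf6, l(3)80Fg, Tsp42Ee, Tcs5 and pths, with signals of 1629 (pths) to 2047 (CG14100).

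Chromosome 4, a small and largely heterochromatic chromosome, was peak-rich. It carried 55 conservative peaks and 1.67 times the density of 2L, 2R, 3L, 3R and X (permutation p = 0.002, two-sided). Over the single-replicate lists the ratio was 2.37 ± 0.569 (SD, n = 3). Chromosome 4 averaged 37.6 ± 1.3 peaks per Mb, while the 5 large arms averaged 15.3 ± 4.87 (3R) to 18.4 ± 5.49 (X) peaks per Mb (SD, n = 3). Promoters, counted after the data were seen, held 47 of the 55 peaks, 85.5% (95% Wilson interval 73.8 to 92.4). The ratio was 2.57 among the 1668 peaks with the highest signal. Against the ranked peaks that did not pass the threshold, of which 0.244% lay on chromosome 4, it was 6.87 as a ratio of odds (Fisher's exact p = 4.57e-26, two-sided). Chromosome 4 has 1.33 Mb of sequence, against 23.5 to 32.1 Mb on each large arm. Those ranked peaks were thus sparse there for its length, and 6.87 partly reflects that background.

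**Figure D2:**
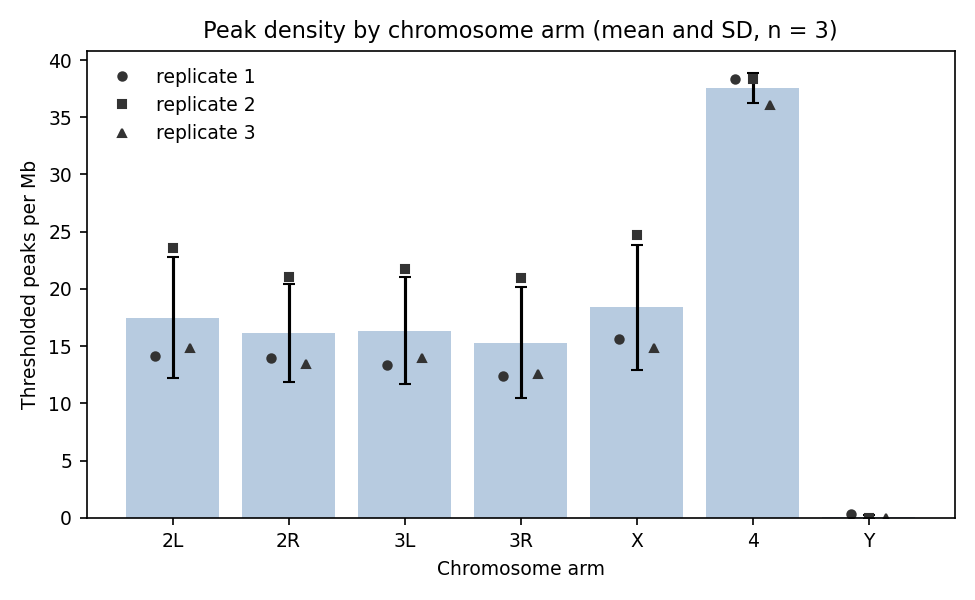
Thresholded peaks per Mb of sequence on each chromosome arm. Bars are means of the 3 replicates, error bars are SD and points are single replicates; chromosome 4 stands at 37.6 peaks per Mb and X, the next arm, at 18.4.

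Pericentric sequence carried few peaks for its length. The intervals next to the centromeres held 195 of 3270 conservative peaks, 5.96%, where random placement gave 13.1%, a ratio of 0.455 (permutation p = 0.002, two-sided). The share was 7.06% ± 0.979 (SD, n = 3) over the single-replicate lists. Against ranked peaks below the threshold, of which 7.78% lay there, the ratio was 0.766 (Fisher's exact p = 8.04e-05, two-sided). Promoters, again counted after the data were seen, held 91 of the 195 peaks (46.7%), and 23 (11.8%) had their summit in an annotated transposable element. Of the 25 strongest peaks, 3 lay in these intervals, at MED21, UQCR-11 and l(3)80Fg.

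The X chromosome had 617 conservative peaks and a density 1.08 times that of 2L, 2R, 3L and 3R (permutation p = 0.102, two-sided). Over the single-replicate lists the ratio was 1.13 ± 0.0398 (SD, n = 3), with a permutation p of 0.016, 0.00999 and 0.148 in replicates 1, 2 and 3. Whether X passes the threshold depends on the peaks taken. The permutation p was 0.00799 without replicate 3 (ratio 1.13), 0.036 for the peaks with the highest signal (ratio 1.15) and 0.977 in the pooled list, where the direction turned (ratio 0.998). With merged entries, chosen after the data were seen, the permutation p was 0.024 (ratio 1.11). Transfer RNA genes were not a frequent location. In the conservative list 8 peaks had their summit within 500 bp of a tRNA gene, 0.24% against 0.178% by random placement (permutation p = 0.486, two-sided). The single-replicate lists went the other way, at 0.323, 0.801 and 0.32 times the random share (mean 0.481 ± 0.277, SD, n = 3), as did the peaks with the highest signal, at 0.359 times and with 1 peak. The single-replicate ratios rest on 1, 4 and 1 peaks (permutation p = 0.332, 0.887 and 0.352, two-sided). Their direction is therefore not established.

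Peaks were frequent at promoters of genes that sit in heterochromatin. A conservative promoter peak was found at 1959 of 13968 protein-coding genes. Among the 26 genes listed as pericentric, 18 had one, 69.2% (Fisher's exact test, adjusted p = 1.46e-09 over 14 lists). Over all 166 protein-coding genes in the intervals, counted after the data were seen, the share was lower, 44.6%. Examples are Dbp80, an RNA helicase gene (3L, 27279111 to 27279404, signal 1105), cta, which encodes a G protein subunit (2L, 22981620 to 22981908, signal 862), RpL38 (2R, 4516440 to 4516703, signal 824) and Alg-2 (3R, 3622963 to 3623200, signal 778). Of the 29 listed chromosome 4 genes, 13 had a peak, 44.8% (Fisher's exact adjusted p = 0.000206). That list holds caps, a 3L gene without a peak, by a wrong match of symbols. With Cadps of chromosome 4 in its place, corrected after the data were seen, 14 of 29 had one (Fisher's exact adjusted p = 3.71e-05). The plexin genes PlexA and PlexB led with signals of 1447 and 1259.6, followed by RpS3A with 1108. Zyx and apolpp shared 1 peak, with a signal of 1031.

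In 4 other lists more genes had promoter peaks than elsewhere. Cytoplasmic ribosomal proteins had peaks at 38 of 93 genes, 40.9%, led by RpS3A, RpL15 (signal 917), RpL38 and RpL5 (signal 731), with an adjusted p of 1.46e-09. Among the peaks with the highest signal this was 23 of 93, 24.7%, still past the threshold. Without 3 ribosomal-like genes that the list took in by name, left out after the data were seen, it was 37 of 90, 41.1%. Insulator and architectural proteins had them at 7 of 16, 43.8% (Fisher's exact adjusted p = 0.0106), with Chro at a signal of 1415, Cp190 at 449, Trl at 245 and pzg at 181. This list holds br by a wrong match, and without it the count, also corrected afterwards, was 7 of 15 (Fisher's exact adjusted p = 0.00677). Cell cycle genes had them at 9 of 27, 33.3% (Fisher's exact adjusted p = 0.0208), with BubR1 at 739, Dp at 432, CycD at 359 and dpa at 203. Heat shock genes had them at 6 of 15 (Fisher's exact adjusted p = 0.0243), with Hsc70-4 at 1519, Hsp27 at 741, DnaJ-1 at 408 and Hsp26 at 140.3. No peak was found at Hsf, Hsp23, Hsp68 or any listed Hsp70 gene. All tests are two-sided. The last 2 calls were not stable. In the list ranked without replicate 2 the adjusted p was 0.128 for cell cycle and 0.0779 for heat shock genes, and in that without replicate 3 it was 0.0569 and 0.0881. They also ended in the pooled list (Fisher's exact adjusted p = 0.0772 and 0.155), with a window of 1000 bp (0.0645 and 0.0607) and with 1 start site per gene (0.0814 and 0.0681), and heat shock genes did so among the peaks with the highest signal (0.286).

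Replication-dependent histone genes had a peak at 0 of 111 (Fisher's exact adjusted p = 4.94e-07). These genes form 1 tandem array on 2L from 21416953 to 21541681, where even the ranked lists held 1, 0 and 3 entries in replicates 1, 2 and 3. Peaks of any rank were nearly absent there and the 111 genes are not independent, so this test does not show less binding. The other lists did not pass the test in any setting, and with so few peaks their shares moved. Hox and segmentation genes had 1 of 29, cad (signal 63.5), with an adjusted p of 0.198. Germline and piRNA genes had 1 of 23, vas (signal 538), with an adjusted p of 0.372. That list holds Nos in place of nanos by a wrong match, and neither had a peak. Neuronal genes had 4 of 24, elav (583), unc-13 (307), onecut (129) and fne (98.2), with an adjusted p of 0.894. Muscle genes had 3 of 19, Actn (386), sls (260.3) and Act87E (143), with an adjusted p of 0.894. Fat body and gut genes had 2 of 19, apolpp and Cat (77.9), with an adjusted p of 1. Genes of heterochromatin proteins had 2 of 24, HP4 (179) and Odj (66.7), with an adjusted p of 0.792. Lsd-2, a lipid droplet protein gene without a peak, was put in that list by mistake, and without it, as chosen after the data were seen, the count was 2 of 23. ZAD zinc finger genes had 3 of 21, M1BP (151), trem (125) and Odj, with an adjusted p of 1. In the pooled list the last 2 lists had 6 of 24 and 6 of 21, and in the list ranked without replicate 3 they had 4 and 5, so genes of heterochromatin proteins turned from a lower share than other genes (odds ratio 0.557) to a higher one (1.68 and 1.26). Without replicate 2 in the ranking they had 1 and 2. The direction also turned in at least 1 setting for ZAD zinc finger, neuronal, muscle, and fat body and gut genes, and germline genes rose to 3 of 23 in the pooled list.

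**Figure D3:**
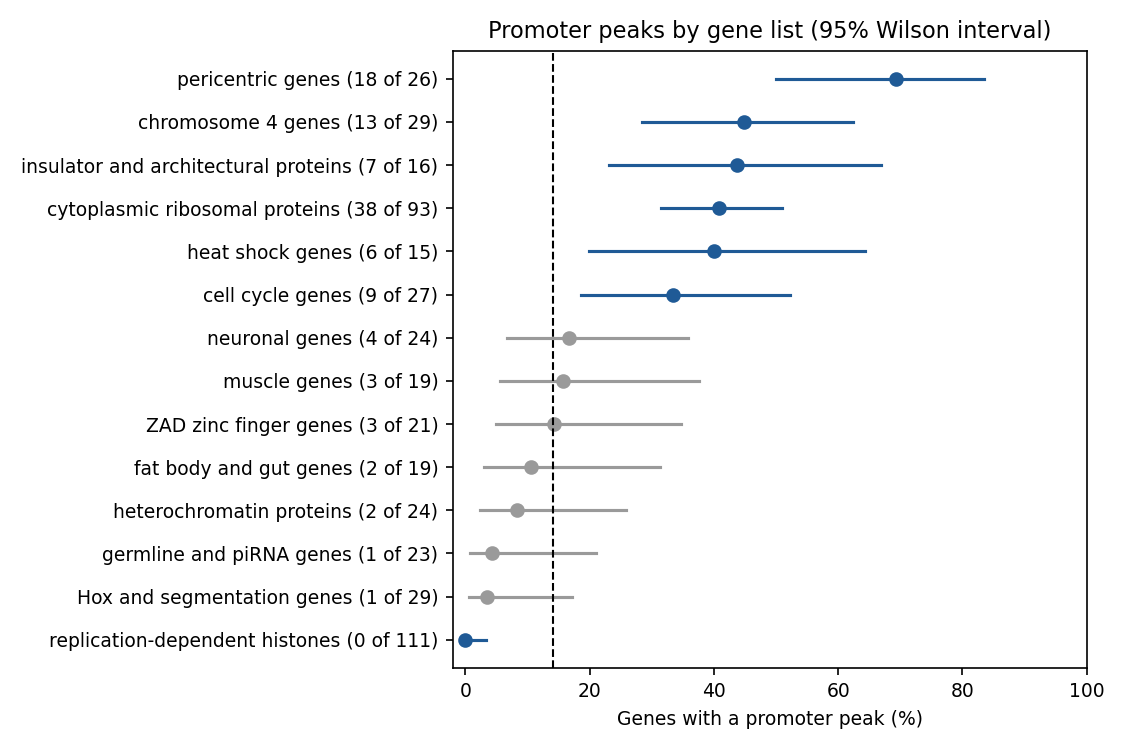
Share of the genes of each list with a conservative promoter peak, in percent. Points are shares, lines are 95% Wilson intervals, blue marks lists past the adjusted threshold and the dashed line marks all protein-coding genes; pericentric genes lie highest at 69.2%.

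Of 8 known sequence elements, 3 were more frequent in the 100 bp around summits than in a 100 bp flank. That flank started 250 bp from the summit toward higher coordinates, whatever the strand of the gene. The TATA box TATAAA was present at 741 of 3327 summits and in 360 flanks (22.3% against 10.8%, exact McNemar adjusted p = 7.53e-35). The DRE element TATCGATA, bound by Dref, was present at 61 summits and in 17 flanks (exact adjusted p = 2.27e-06). The BEAF element CGATAR was present at 311 and 230 (exact adjusted p = 0.000513). A TATCGATA also counts as CGATAR where A or G follows it or C or T precedes it. The DRE and BEAF results are therefore not separate, here or with the other flanks, and the sites in common were not counted. GAGAGAG, bound by Trl, and the E-box CACGTG were less frequent at summits, at 37 against 85 and 26 against 47 (exact adjusted p = 3.71e-05 and 0.0298). The elements of M1BP (13 against 6), Zelda (12 against 20) and GATA factors (48 against 41) did not pass. All tests are two-sided and adjusted over the 8 elements. The M1BP element passed without replicate 2 or without replicate 3 (exact adjusted p = 0.0256 for each) and in windows of 200 bp (48 against 18, exact adjusted p = 0.000459). With the flank on the side of lower coordinates the direction of M1BP turned (13 against 14). CACGTG kept its direction but no longer passed among the peaks with the highest signal (9 against 21, exact adjusted p = 0.0684) or in windows of 200 bp (64 against 88, exact adjusted p = 0.0777). Against a flank matched on A/T content, chosen after the data were seen, GAGAGAG (37 against 42) and CACGTG (26 against 32) no longer passed (exact adjusted p = 0.774 for each). The other 3 did, though that flank stayed less A/T-rich than the summits. In the 1294 peaks with a flank of exactly the same A/T count, also chosen after the data were seen, TATAAA was present at 221 summits and in 216 flanks and no longer passed (exact adjusted p = 1). There TATCGATA (29 against 12) and CGATAR (134 against 96) still passed (exact adjusted p = 0.046 for each). GAGAGAG was equal in both, at 19 against 19, while CACGTG stayed less frequent at summits, at 11 against 20, without passing (exact adjusted p = 0.399). Promoters without a peak were not compared, so none of these counts separates bound sites from promoters in general.

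Summits were A/T-rich, with a mean A/T content of 65.7% in the 100 bp window and 56.8% in the flank. Of 8185 words of 7 bases tested, 815 were more frequent at summits and 1248 less frequent (exact McNemar test, adjusted p under the threshold of 0.05). The word TTTAAAA was present at 471 summits and in 179 flanks (exact adjusted p = 5.74e-30), AAAATAT at 521 and 245 (adjusted p = 4.36e-23), ATATAAA at 341 and 153 (adjusted p = 1.45e-15) and AATAATT at 335 and 161 (adjusted p = 2.01e-13). The repeat word CACACAC was present at 58 and 210 (exact adjusted p = 2.58e-19). With an A/T-matched flank, chosen after the data were seen, 108 words were more frequent at summits and 80 less frequent. With the flank of exactly the same A/T count 5 were more frequent, and TTTAAAA was present at 121 summits and in 106 flanks. Words could also be less frequent there, as AACAAAA was, at 80 against 149 (exact adjusted p = 0.00365).

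Odj had a conservative peak at its own promoter and danr did not. The Odj gene (FBgn0038551) lies on 3R from 17807407 to 17809222, and its peak ran from 17808695 to 17809074, with a signal of 66.7, at percentile 9.47 of the list. The summit of this peak lay 337 bp downstream of the start site, while most promoter summits lay upstream. No single-replicate thresholded list overlapped the peak. The peak nearest danr (FBgn0039283; 3R, 25138072 to 25139903) lay 14.6 kb away. In the 40 kb around each gene the number of ranked peaks was 30.7 ± 8.08 for Odj and 27.7 ± 2.08 for danr (SD, n = 3). Among 1000 random windows of 3R these stood at percentiles of 62.2 ± 21.5 and 49.8 ± 26.8 (SD, n = 3). The loci lay further apart in windows of 20 kb (72.6 ± 17.5 and 26.6 ± 8.78) and 80 kb (57.2 ± 15.8 and 22.4 ± 8.33). By these counts of ranked peaks of any strength neither locus stood apart from the arm. Thresholded peaks in the same 40 kb numbered 0, 5 and 1 around Odj and 0 in each replicate around danr. The whole of 3R held 12.4, 20.9 and 12.6 thresholded peaks per Mb in replicates 1, 2 and 3. Neither difference, between the loci or from the arm, was tested. The labels' conflict is left open.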

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

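The tests of words with C or G and of peaks outside promoters were chosen only after their results could be seen. The other tests of technical causes in this part were specified after the patterns they address had been seen and before their own values were. The test of A/T-only words was added after the first matched flank had given no clear answer. Some entries with a passing score stand outside the lists that every comparison used. The thresholded lists left out 34 ranked entries at or above the lowest score they keep in replicate 1, 33 in replicate 2, 19 in replicate 3 and 35 in the conservative list. Of these, 32, 31, 17 and 32 lay on unplaced or Y scaffolds, and the reason for leaving them out is not given in the sources used here. The strongest left-out entry of the conservative list had a signal of 533, but the median was 129, against 144 for the entries kept. In the lists of replicates 1, 2 and 3 the left-out medians were lower as well (58.6, 49.8 and 50.5 against 69.9, 65.2 and 70.3).

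A/T-rich words filled the summits, and base composition alone is a candidate explanation. With a flank matched on A/T content, 12.1% of the 815 words were called again, between the bounds of 10% and 50% set for that test, and the match left the flank at 63.4% A/T against 65.7% at summits. In the 1294 peaks with a flank of exactly the same A/T count, 46.9% of the 64 words made of A and T alone were present at more summits than flanks, which for that set is consistent with A/T content. With the same equal flank, 5 words with C or G were called higher at summits, CACAGTG at 60 against 13, so A/T content is argued against for those 5. For the other words composition cannot be told apart from binding, because the closest flank was not equal and the equal one keeps few peaks; no biological explanation was tested.

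Few peaks lay in pericentric sequence, at 0.455 times the random share. Reads that are hard to place stay open as a cause. The thresholded share was 0.766 times that of ranked peaks below the threshold, past the bound set for arguing against that cause. This ratio cannot decide, because such a loss may take strong peaks more than weak ones. The sets also differ in promoters, which held 50.2% of thresholded and 13.9% of the other ranked peaks. Of those other peaks 7.78% lay in the intervals, against 13.1% by random placement, so such a loss could explain part. Only 166 of 13865 protein-coding genes on these arms (1.2%) lie there, a shortage larger than that of peaks, so their 3.31 times higher share with a promoter peak (44.6% against 13.5%) does not speak against a lack of promoters, and the bound set for that test was wrong. Peaks outside promoters were also few, 104 of 1646 at 0.426 times the share of random places outside promoters (permutation p = 0.002, two-sided), which argues against fewer promoters as the cause for those peaks. With the intervals 1 Mb larger or smaller on each arm the ratio was 0.515 or 0.344 (permutation p = 0.002 for each, two-sided), which argues against errors of that size in the bounds. Entries at the cutoff left out of the conservative list numbered only 3 on the arms, too few to make up the shortage. A lack of promoters for promoter peaks and any earlier filters of the authors stay open, and no biological explanation was tested.

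Replicate 2 had 1.6 times as many peaks as replicate 3. Its 1075 peaks that neither other thresholded list overlapped had a median signal percentile of 94 in the ranked list of replicate 1 and 93.2 in that of replicate 3. Shared peaks had 99.2 and 99. Those ranked lists held 97839 and 85970 entries, against 1891 and 1889 past the threshold, so the medians lay well below the cutoff. The medians met the bound set for a cutoff that fell at another rank, and most of the sites had a ranked peak in the other replicates. No ranked peak was there for 99 and 112 of them in replicates 1 and 3. No random share is given for this overlap, so it cannot tell a moved cutoff from weak peaks that overlap by chance. Depth, which is unknown here, stays open, and no biological explanation was tested because the replicates form 1 group.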

How the results depend on the processing

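Merged entries, corrected gene list members, the A/T-matched and exactly matched flanks and the 9-base words were chosen after seeing the data. The list without replicate 1 is the conservative list itself and tests nothing, and the lists without replicates 2 and 3 leave them out of the ranking only. Of the 96 other alternatives to the main results, 72 gave the same result, 19 moved in size (1 by construction), 3 passed the threshold where the main test did not, and 2 turned direction. In the 220 alternatives for single gene lists and elements, 18 calls ended (cell cycle and heat shock genes, E-box, GAGA, TATA) and 3 were gained (M1BP). The promoter, pericentric and chromosome 4 results kept direction and call in every alternative run, at 2.57 to 5.31, 0.344 to 0.766 and 1.38 to 2.57 times the background, with 6.87 for chromosome 4 as a ratio of odds against ranked peaks. Gene lists past the threshold numbered 5 to 7, which counts as the same although 2 calls ended. Above the common median signal the mean per replicate is 1132, which that cutoff fixes. The Spearman correlation of signal rose to 0.854 and 0.899 with summits within 100 bp for replicates 1 and 2 and replicates 1 and 3, and Pearson's r of log10 signal was 0.752, 0.793 and 0.782. The share of peaks in all 3 replicates was 39.0% and 37.1% under the stricter overlap rules, 31.1% in the pooled list, 77.8% in the upper 50% by signal and 43.9% and 48.6% without replicates 3 and 2, against 42.0% in the conservative list. The X ratio was 0.998 in the pooled list, 1.15 in the upper 50% by signal, 1.11 with merged entries and 1.09 and 1.13 without replicates 2 and 3, against 1.08 in the conservative list; the tRNA ratio was 0.359 in the upper 50% by signal. The danr percentile was 22.4 in 80 kb and 26.6 in 20 kb, and that of Odj was 57.2 and 72.6. Elements passing numbered 3 with the A/T-matched flank and 2 with the exactly matched one. Words more frequent at summits numbered 431 with 6 bases, 108 with the matched flank, 5 with the exactly matched one and 12 with 9 bases and the A/T-matched flank in the 832 strongest peaks, where 7 bases and that flank gave 32. Shorter and longer words change how many are tested, and the exact match keeps only 1294 peaks. Other causes were not tested, and unknown depth limits the comparison of replicates.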

Other observations

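All values in this part come from tests chosen after seeing the data. Gene families differed widely. Mediator subunits had a conservative promoter peak at 10 of 25 genes, among them MED21, MED26 and MED1 with signals of 2099, 809.5 and 547. Mitochondrial ribosomal proteins had one at 20 of 73 (27.4%), led by mRpL41 and mRpS10 (signal 1429), and tetraspanins at 10 of 34 (29.4%), where Tsp42Ee and Tsp42Ed share 1 peak. Odorant receptors (0 of 59), gustatory receptors (0 of 60) and cuticular proteins (0 of 70) had none, odorant-binding proteins had 1 of 51 and cytochrome P450 genes 3 of 83. Against other protein-coding genes, adjusted p over 12 families was 0.00377 for Mediator, 0.00741 for mitochondrial ribosomal proteins, 0.0318 for tetraspanins, and 0.000927, 0.000927, 0.000478, 0.0129 and 0.00741 for the 5 depleted families in the order given (Fisher's exact test). TBP-associated factors (5 of 15), NADH dehydrogenase subunits (9 of 40), vacuolar ATPase subunits (7 of 33) and proteasome subunits (6 of 48) did not pass.

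Genes with a divergent neighbour starting within 1 kb had a promoter peak at 1097 of 4648 (23.6%), against 862 of 9320 other genes (9.25%), with an odds ratio of 3.03 (Fisher's exact p = 1.14e-110). A peak between 2 such genes counts for both, which raises the first share and the odds ratio. Such genes are not independent, so this p overstates the evidence. On chromosome 4, 40 of 80 protein-coding genes had a peak, against 13.5% on the 5 large arms outside the pericentric intervals (Fisher's exact p = 7.6e-15).

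Among the strongest peaks, a pair of related 9-base words stood out. In the 832 peaks with the highest signal, AGTGGAAAC was present at 30 summits and in 1 A/T-matched flank, and AGTGTGAAC at 31 and 2 (exact McNemar adjusted p = 2.22e-05 for each, over 1487 words). On the other strand AGTGTGAAC reads GTTCACACT, which differs from the M1BP element GGTCACACT in 1 base. This setting was picked from 9 scans of words of 7, 8 and 9 bases in all peaks, the 832 strongest and the 1664 weakest. Over all 3327 peaks the counts were 40 against 4 and 41 against 7. In the 1664 peaks with the lowest signal they were 9 against 3, which did not pass, and 7 against 2, too few to be tested. With a flank of exactly the same A/T count, 5 words of 7 bases were more frequent at summits, CACAGTG (60 of 1294 summits against 13 flanks, exact McNemar adjusted p = 9.58e-05), GTGTGAA (57 against 18), CAGTGCA (49 against 15), ACAGTGG and CACTGTA (45 against 15 each). These words are not separate. CACAGTG, ACAGTGG, CAGTGCA and the reverse strand of CACTGTA share CAGTG, and GTGTGAA lies within AGTGTGAAC.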
